A study of Arabidopsis thaliana with 3 samples.

How the data were processed

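Gene expression was measured in Arabidopsis thaliana plants on 3 two-colour microarrays, each carrying RNA of the hy5-1 mutant and RNA of its wild type Landsberg erecta (Ler). HY5 encodes a bZIP transcription factor of light signalling. Per the labels, plants were grown for 3 weeks at 22 °C under 16 h of light and 8 h of darkness and then kept for 1 day at 4 °C. Each array was labelled as a biological replicate. RNA was extracted with Trizol and purified on columns, and aminoallyl-labelled amplified RNA was coupled to the dyes, per the labels' protocols. The hy5-1 RNA was labelled red (Cy5, Hyper5) and the Ler RNA green (Cy3) on all 3 arrays. No array had the dyes exchanged, so a dye effect of a probe could not be separated from a difference between the genotypes.

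The deposited values were taken as log2 ratios of the 2 channels, given for 45220 features per array with no missing value. The base of the logarithm, the normalisation, the scanner software and the numerator of the ratio are not given in the sources used here. Base 2 was assumed because the values reached 5.09, which in base 10 would be an implausible ratio. The arrays averaged 0, and their medians were 0.01, 0 and 0 for replicates 1, 2 and 3, so the values appeared to have been centred. A positive value was read as higher in hy5-1, that is Cy5 over Cy3, which is the likely direction at most. The sample titles put Ler before the mutant, so the opposite reading stays open, and all directions would then turn together.

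Genes were named through the platform annotation supplied for the value table and the RefSeq gene table of assembly TAIR10.1. All 7440 named features had a single gene, none had several, and 37780 features were not named here, among them control spots that could not be told from the rest. The named features covered 7234 loci. The row numbers of the values did not follow the feature numbers of the annotation. With the numbers used as given, the features of 7 genes spotted 10 times or more differed as much within a gene as between genes, with a variance ratio of 1.009. Among 33 orderings compared, most of them of a grid of 266 columns and 170 rows, the array maker's feature order read along rows brought this ratio to 0.043. The next best ordering gave 0.858, and 1000 permutations gave 0.751 to 1.088. All 7 genes separately had their smallest variance under this ordering. The 132 genes with 2 or 3 different features separated the orderings poorly: their ratio was 0.907 under this ordering and 0.948 with the numbers as given, and other orderings went as low as 0.879. Residuals of neighbouring rows correlated at 0.073 and those of rows 266 apart at 0.071, as a grid numbered along rows would give. This ordering was found from the values and was used throughout. Every gene name in the text rests on it.

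Features of a locus were averaged, and the mean log2 ratio of each locus was tested against 0 with limma (version 3.58.1 in R 4.3.3), by an intercept fit over the 3 arrays with empirical Bayes moderation. The p-values were adjusted by the Benjamini-Hochberg method over the 7234 loci, with a threshold of 0.05. Values were used as deposited, without new centring. The array number limited the precision, since 3 arrays leave 2 residual degrees of freedom and the prior added 3.04. The deposited table gave ratios without intensities, so signal over background was unknown. The procedure was tested on simulated ratios for the 7234 genes of hy5-1 against Ler, with 200 of them changed. It recovered 95.3% of genes changed by 2 on the log2 scale, 79.0% of those changed by 1 and 9.46% of those changed by 0.5, with 6 false calls among 123. In a second simulation with 1200 genes changed by 0.8, 1066 were recovered, with 51 false calls. With no gene changed, 0 genes passed. A dye effect of a probe shared by the 3 arrays would pass as a change, and the simulations give no bound on it.

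Before the data were examined, 24 gene lists with 371 genes were fixed. They covered flavonoid and anthocyanin enzymes and regulators, phenylpropanoids, cold regulators, COR and LEA genes, cold-related sugar metabolism, light harvesting, rubisco, chlorophyll, antioxidants, light signalling, UV-B protection, the clock, auxin, abscisic acid, salicylate and jasmonate, nutrient assimilation, cell wall loosening, heat shock, reference genes, and markers of flowers, roots and senescence. Only 40 listed genes had a named feature, 13 lists had none, and 7 lists had the minimum of 3 measured members. Those 7 were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The rule for named genes, also fixed beforehand, took HY5, the 10 largest positive and 10 largest negative means among genes past the threshold with the same sign on all 3 arrays and a probe assigned to 1 locus, and list members past the threshold, up to 4 per list. HY5 had no named feature and was not analysed here. Calls were counted per chromosome and among 50 named loci on each side of HY5, ordered by locus number, with Fisher's exact test. The number 50 was set after the arrays were first fitted but before any window was counted.

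Alternatives fixed beforehand were median centring, scaling to a common median absolute deviation, robust moderation, an unmoderated statistic, a fit per probe, a rule requiring 2 arrays, a 2-fold minimum, removal of the genes with an SD above percentile 95, each array left out in turn, and a window around HY5 of double width, which became 100 loci per side once 50 had been set. Row numbers as given, a joint test of all features and scaled arrays for the window were added after the data had been seen.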

Results

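Transcript ratios between cold-treated hy5-1 and Ler plants were available for 3 biological replicates, each on its own array and each as a log2 ratio of mutant over wild type under the likely reading of the deposited sign. The title of the series places the comparison in the regulation of cold-induced genes by the transcription factor HY5. Plants of both genotypes had spent 1 day at 4 °C, so the arrays compared genotypes in the cold and not cold with warmth. Named loci numbered 7234. Over these genes the ratios correlated at r = 0.759 between arrays 1 and 3, at 0.512 between arrays 1 and 2 and at 0.504 between arrays 2 and 3. These correlations are across genes, which are not independent replicates. The HY5 transcript itself was not analysed here, so the genotype of the labelled RNA was not checked by its own gene.

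Among genes past the threshold, those furthest below wild type in hy5-1 were AT3G44870, a member of a methyltransferase family with a close neighbouring copy, and AT3G01060. AT3G44870 had a mean log2 ratio of -2.12 ± 0.19 (SD, n = 3), a 4.35-fold lower level with a limma adjusted p of 0.0168, and AT3G01060 had -2.08 ± 0.11 (SD, n = 3). SIR (AT5G04590), the sulfite reductase of sulfur assimilation, was 3.15-fold lower, at -1.66 ± 0.33 (SD, n = 3). AT2G07698, annotated as an alpha subunit of the mitochondrial ATP synthase, stood at -1.84 ± 0.15 (SD, n = 3). A near-identical copy lies in the mitochondrial genome, and the ratio was not shown to be free of it. The remaining genes of the 10 lowest past the threshold were AT5G46780, AT5G44400, AT3G05900, AT5G03460, AT3G27550 and AT3G17800, with means from -1.86 to -1.68. AT5G46780 encodes a VQ-motif protein and AT5G44400 a protein of the berberine bridge enzyme family. Each of these 10 genes had a single named feature, so its ratio was that of a single probe.

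Among genes past the threshold, those furthest above wild type in hy5-1 were AT1G47980, at 1.75 ± 0.96 (SD, n = 3), and LHCB4.3 (AT2G40100), a minor antenna protein of photosystem II. LHCB4.3 was 2.66-fold higher, at 1.41 ± 0.13 (SD, n = 3), with a limma adjusted p of 0.0168. PSBW (AT2G30570), a small subunit of photosystem II, was 2.19-fold higher at 1.13 ± 0.39 (SD, n = 3). AT4G28140, an AP2/ERF transcription factor, reached 1.28 ± 0.57 (SD, n = 3). AT5G33370, a GDSL-type lipase, reached 1.15 ± 0.45 (SD, n = 3). The other 5 genes of this group were AT4G20420, AT4G08910, AT2G20870, AT4G04630 and AT5G59410, with means from 1.37 down to 1.09.

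**Figure D1:**
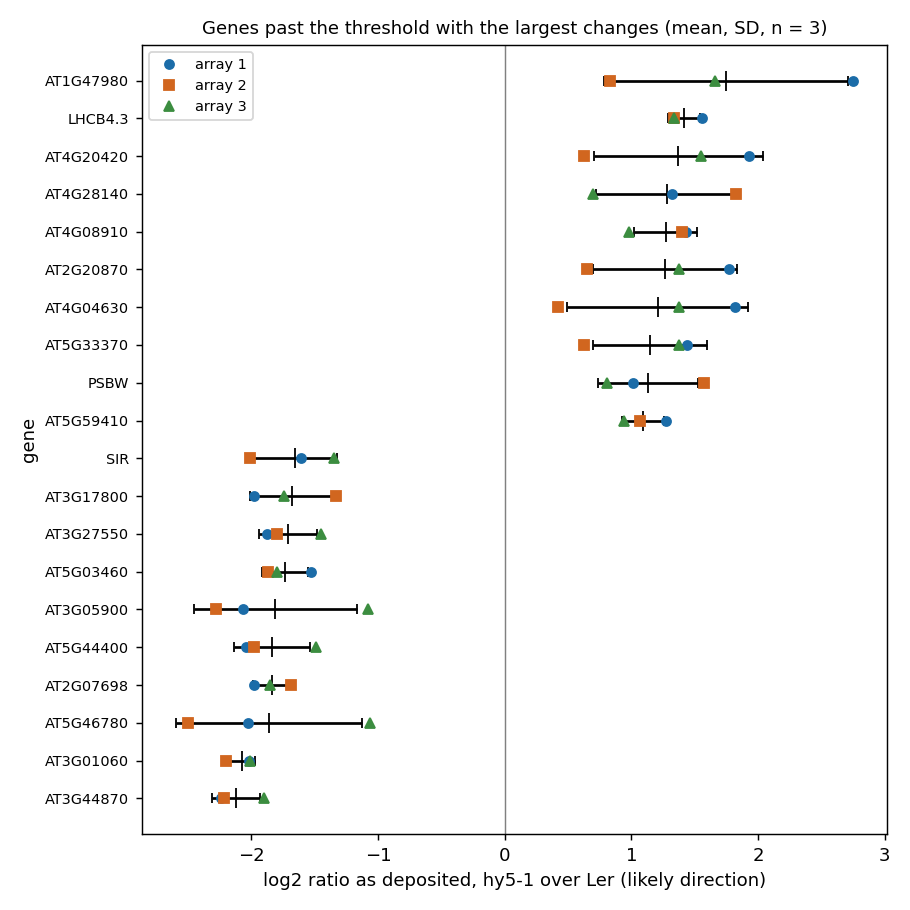
Log2 ratio of hy5-1 over Ler (horizontal axis, likely direction) for the 10 genes highest above and the 10 furthest below wild type among those past the threshold. Coloured marks are the 3 arrays, vertical ticks the mean and bars the SD; LHCB4.3 lies between 1.34 and 1.56 and AT3G01060 between -2.20 and -2.01, whereas AT1G47980 spreads from 0.83 to 2.75.

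In all, 1242 of 7234 genes passed the threshold, 570 higher and 672 lower in hy5-1. All 1242 had the same sign on the 3 arrays, which passing a test on 3 arrays nearly fixes in advance. Of all 7234 genes, 54.5% had the same sign on all 3 arrays, against 25% expected by chance. A dye effect of a probe would also keep its sign. At an unadjusted p under 0.05 there were 2627 genes. Of 151 genes past the threshold with a change of 2-fold or more, 18 were higher and 133 lower in hy5-1 under the likely direction, and under the opposite reading of the sign 133 would be higher and 18 lower. Without replicate 1 or without replicate 3 limma called 0 genes, with 1613 and 1585 genes at an unadjusted p under 0.05, whereas without replicate 2 it called 1380, 946 of them shared. With the arrays scaled to a common median absolute deviation, 391 genes passed. All lay close to the threshold, since the smallest limma adjusted p was 0.0494. Over all features, the scaled median absolute deviations were 0.2076, 0.1334 and 0.1927 on arrays 1, 2 and 3. The SDs were 0.3774, 0.3852 and 0.3206. Array 2 had the smallest deviation but the largest SD, so this scaling enlarged its ratios and did not make the SDs equal. An unmoderated statistic called 3 genes, 1 of them among the 1242. There a gene with equal values on all 3 arrays was given a p of 0. The smallest adjusted p of that statistic was 0, so the 3 included such a tie. Scaling ended the call of 10 of the 25 named genes, namely SIR, PSBW, AT4G28140, AT4G04630, AT5G46780, AT3G05900, PRXQ, GR1, GI and IAA29, with limma adjusted p-values from 0.0505 to 0.116. The dyes were never exchanged, so dye and genotype were confounded. Among 132 genes with different features, the mean ratios of 2 features correlated at only r = 0.242 (permutation p = 0.00556, two-sided, across genes). Each of the 25 named genes had a single named feature, so its ratio could not be checked on another feature.

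Among the light-harvesting proteins, 3 members of the LHCB4 family (CP29) were measured, and they differed in direction. LHCB4.3 rose and LHCB4.1 (AT5G01530) fell, the latter with a mean of -0.60 ± 0.09 (SD, n = 3) and a limma adjusted p of 0.0238. LHCB4.2 (AT3G08940) had 0.69 ± 0.47 (SD, n = 3) and did not pass over all genes (adjusted p = 0.067). Adjusted over the list alone, 2 members rose and 1 fell. The calls of LHCB4.3 and LHCB4.1 also passed with the arrays scaled to a common median absolute deviation, but only just (limma adjusted p = 0.0494 for both). That was the smallest adjusted p of the scaled fit, so all its calls lay close to the threshold. The list as a whole showed no shift with limma's camera (adjusted p = 0.877; adjusted p = 0.96 with an estimated correlation).

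The flavonoid and anthocyanin enzymes had 8 measured members, and 0 passed the threshold, also when adjusted over the list alone. Of the 8, 5 differed in sign between arrays and 3 were below 0 on all arrays. DFR (AT5G42800), dihydroflavonol reductase of the anthocyanin branch, had 2.61 on array 1, -1.64 on array 2 and 2.28 on array 3. The anthocyanin glucosyltransferase UGT75C1 had 1.97, -0.30 and 2.00, and the malonyltransferase 5MAT had 2.02, -0.84 and 1.89 on the same arrays. The coumaroyltransferase 3AT1 had 1.58, -1.82 and 1.38. UGT78D1, a flavonol rhamnosyltransferase, was below 0 on all 3 arrays, at -0.75, -3.72 and -1.48, with an adjusted p of 0.0712. UGT78D2 and UGT89C1 were also below 0 throughout, with smaller means of -0.52 and -0.34. UGT78D3 had 0.54, -0.37 and 0.64. The list had a mean of 0.14 and a median of 0.33 over members, with a camera adjusted p of 0.877. Its mean turned to -0.06 with scaled arrays, to -0.25 without replicate 1 and to -0.17 without replicate 3, and stood at 0.84 without replicate 2.

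**Figure D2:**
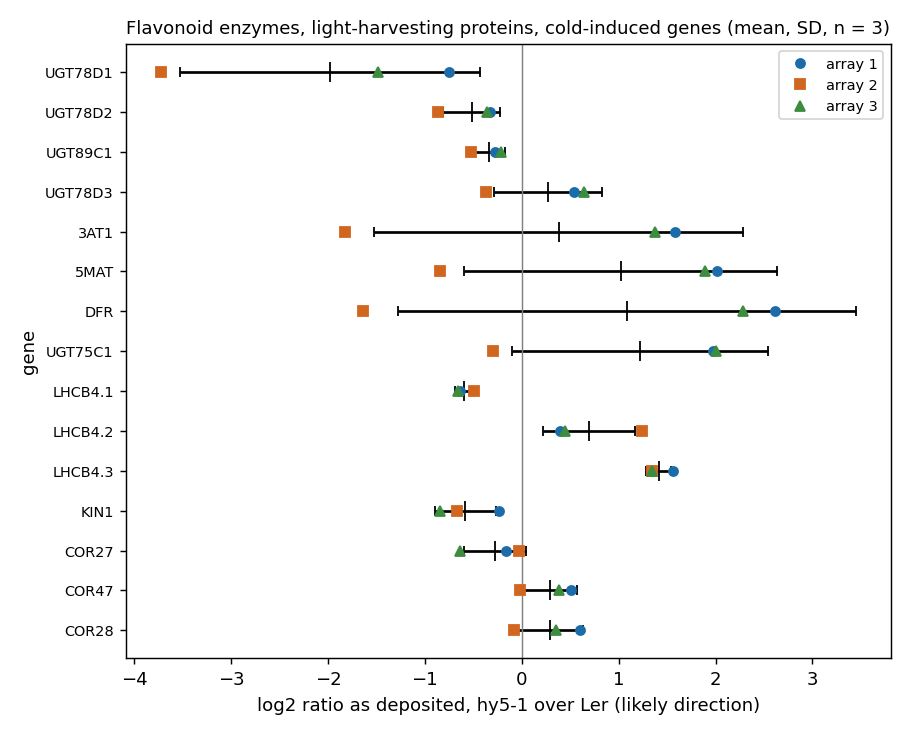
Log2 ratio of hy5-1 over Ler (horizontal axis, likely direction) for the measured members of 3 lists: flavonoid and anthocyanin enzymes (UGT78D1 to UGT75C1), light-harvesting proteins (LHCB4.1 to LHCB4.3) and cold-induced genes (KIN1 to COR28). Coloured marks are the arrays, vertical ticks the mean and bars the SD; array 2 is lowest for all 8 enzymes, as for DFR at -1.64 against 2.61 and 2.28.

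Of the cold-induced COR and LEA genes, 4 were measured and 0 passed over all genes. KIN1 (AT5G15960), a small hydrophilic cold-induced protein, came closest at -0.58 ± 0.31 (SD, n = 3) with a limma adjusted p of 0.0535, and it was lower on 3 of 3 arrays. Adjusted over the list alone, 1 member fell. COR47 and COR28 both had means of 0.29, and COR27 had -0.28. The list median was 0.01 and its mean -0.07, which differ in sign, with a camera adjusted p of 0.877. KIN1 has a close homologue next to it, and its ratio was not shown to be free of that copy.

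Among the antioxidant enzymes 2 of 7 measured members rose and 5 did not pass. PRXQ (AT3G26060), a chloroplast peroxiredoxin, was at 0.71 ± 0.39 (SD, n = 3) and GR1 (AT3G24170), a glutathione reductase, at 0.54 ± 0.14 (SD, n = 3), with limma adjusted p-values of 0.0466 and 0.0314. The same count of 2 was obtained when adjusted over the list alone. With scaled arrays neither passed over all genes, at adjusted p-values of 0.116 for PRXQ and 0.0737 for GR1. The mean of the list was 0.15, with a camera adjusted p of 0.877.

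The evening clock gene GI (AT1G22770) fell by 0.73 on the log2 scale, with an SD of 0.37 over 3 arrays and a limma adjusted p of 0.0404, and was the only measured member of the clock list. IAA29 (AT4G32280), an auxin-responsive repressor, fell by 0.68 with an SD of 0.25 and an adjusted p of 0.031. With scaled arrays neither passed, at adjusted p-values of 0.0524 for GI and 0.079 for IAA29. GH3.3, the other measured member of the auxin list, was at 0.09 ± 0.37 (SD, n = 3). Chlorophyll biosynthesis had 0 of 7 measured members past the threshold, with means from -0.31 for GSA1 to 0.26 for CHLM. Expansins and xyloglucan endotransglucosylases had 0 of 3, with EXPA4 at 0.55 and EXPA8 at -0.35. Adjusted over the list alone, EXPA4 rose and EXPA8 fell. The phenylpropanoid enzyme HCT was at 0.35 and the root marker EXPA18 at 0.06, neither past the threshold over all genes. HCT was the only measured member of its list, so over the list alone its limma p of 0.0212 needed no adjustment and passed. The reference genes GAPC2, EF1A and TIP41 were at 0.08, 0.02 and 0.26, with 0 of 3 past the threshold. Camera called 0 of 7 lists, as did camera with an estimated correlation (adjusted p = 0.96 for each list) and fry's directional test. Before adjustment, 0 lists by camera and 1 by fry, the light-harvesting proteins (limma adjusted p = 0.139), had a p under 0.05. Fry's mixed test asks for change in either direction and was read after the directional tests. It passed for the light-harvesting proteins alone (limma adjusted p = 0.0102 over 7 lists), with 3 measured members, LHCB4.3 among them. The test sets a list against no change and not against the other genes, many of which passed. It therefore does not show this list to be particular. Chlorophyll biosynthesis, with 0 of 7 members past the threshold, had a limma adjusted p of 0.0915 in fry's mixed test.

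Genes past the threshold were more frequent around the HY5 locus than elsewhere. Of 100 named loci flanking HY5 on chromosome 5 (neighbours taken from assembly TAIR10.1), 29 passed, or 29.0%, against 17.0% elsewhere (Fisher's exact test, two-sided, p = 0.00301, adjusted p = 0.0211 over 7 tests of position). They included AT5G11230 at 0.99 ± 0.45 (SD, n = 3) and AT5G11240 at -0.89 ± 0.18 (SD, n = 3), both named here for their place close to HY5 after their values were seen. In the window of 200 loci the share was 23.0% (Fisher's exact test, p = 0.0358, adjusted p = 0.0836). Of the 29 genes, 14 were higher and 15 lower in hy5-1. By chromosome the share ran from 15.8% on chromosome 1 to 19.5% on chromosome 4, and no chromosome differed from the others after adjustment.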

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

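The count below was added after the data had been seen. Signal also appeared in features outside the named genes. When all features were tested together with limma, 2130 of the 37780 features not named here passed the threshold, 1085 higher and 1045 lower in hy5-1. That is 5.64% of them, against 12.98% of the named genes in the same test. No gene is given for these features, and control spots among them were not removed.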

How the results depend on the processing

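Row numbers as given, the joint test of all features and both added window settings were chosen after the data had been seen. The counts of all, higher and lower genes (1242, 570 and 672) stayed within 1.5 times under median centring, robust moderation, the fit per probe, the rule of 2 arrays (no value was missing, so it changed nothing) and the joint test. They became 391, 166 and 225 with arrays scaled to a common median absolute deviation (smallest limma adjusted p 0.0494). With an unmoderated statistic they were 3, 2 and 1, with a gene of equal values on all arrays, given a p of 0, among them. They were 151, 18 and 133 with a 2-fold minimum, and 491, 242 and 249 with row numbers as given. Without the noisiest genes they were 1879, 905 and 974. Leaving out an array gave 0 to 1380, 0 to 655 and 0 to 725 genes by limma, with 0 in each count without replicate 1 or without replicate 3. The cause was not tested for these changes. The window around HY5 held 23.0% past the threshold at double width, against 17% elsewhere. With scaled arrays it held 11% against 5.33% elsewhere (odds ratio 2.2, p = 0.0224, Fisher's exact test). With row numbers as given it held 8.0% against 6.77% elsewhere (odds ratio 1.2, p = 0.55, Fisher's exact test). Lists past the threshold of a directional test numbered 0 in every setting run. The mean of the flavonoid list turned from 0.14 to -0.059 with scaled arrays and ran from -0.246 to 0.844 with an array left out (below 0 without replicate 1 and without replicate 3). That of chlorophyll biosynthesis, 0.013, ran from -0.073 (without replicate 2) to 0.067. All 25 named genes had the same sign on all 3 arrays, so these settings could hardly turn their direction. All 25 lost their call without replicate 1, without replicate 3 and with the unmoderated statistic, and 10 with scaled arrays. The alternatives for HY5 itself were not run, since it had no named feature. Signal over background is unknown, so no limit from dim spots can be given. No paired analysis was possible because all 3 arrays form a single group and each ratio already pairs the genotypes.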

Other observations

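The gene families, the named genes of this paragraph and all tests below except that of windows along the chromosomes were chosen after the data had been seen. Among named genes with an established symbol, picked by no rule fixed beforehand, several stood well below wild type in hy5-1. CUL4 (AT5G46210), the cullin of a ubiquitin ligase, was at -1.34 ± 0.25 (SD, n = 3), TIC (AT3G22380), a clock regulator, at -1.50 ± 0.27 (SD, n = 3), and UPF3 (AT1G33980), a factor of nonsense-mediated decay, at -1.07 ± 0.16 (SD, n = 3). Their limma adjusted p-values were 0.0169, 0.0168 and 0.0169. Without replicate 1 or without replicate 3 limma called 0 genes, so these calls were lost there too. On the other side, ATG8D (AT2G05630), an autophagy protein, was at 0.83 ± 0.26 (SD, n = 3) and VPS60.2 (AT5G04850) at 0.98 ± 0.32 (SD, n = 3).

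Of 14 gene families with 8 or more named members, grouped by the letters of their symbols, 0 shifted by camera after adjustment. Among 36 UGT glycosyltransferases 0 rose and 5 fell (adjusted p = 0.273; adjusted p = 0.819 with an estimated correlation). Among 11 BGLU glucosidases 0 rose and 3 fell (adjusted p = 0.273; adjusted p = 0.819 with an estimated correlation). Over all tested genes 17.2% passed, a share that 5 of 36 UGT genes did not reach and 3 of 11 BGLU genes exceeded.

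All 8 flavonoid and anthocyanin enzymes were lower on array 2 than on the other 2 arrays, with a mean departure of -2.1. Exchanged dyes on array 2, against the labels, would turn the genotype part of its ratios but not the dye effects of probes. The lower of its correlations with the other arrays was 0.504. This cannot decide the question, because dye effects shared by the arrays would also keep the correlation above 0. With dyes exchanged on array 2, genes with the same sign on all 3 arrays would mainly show dye effects. All 1242 calls are such genes. A local flaw would also touch neighbouring spots, but the median departure of 64 neighbours was 0.055. Independent noise would not move together a list whose members were fixed beforehand, and random sets of 8 genes departed as far with a permutation p of 1e-05 (the smallest that 100000 draws can give; adjusted p = 7e-05 over 21 tests of 7 lists on 3 arrays). The p was the same for arrays 1 and 3, whose departures are tied to that of array 2. The departure was not confined to this list. Of 14 named genes above 1 on arrays 1 and 3 and below 0 on array 2, 10 were outside it. AT1G29470 was among these 10, with a departure of -4.42. In the opposite direction, 4 named genes were below -1 on arrays 1 and 3 and above 0 on array 2. AT3G15356 was among these 4, with a departure of 3.07. A difference between the plants of replicate 2, in either genotype, may remain as a candidate explanation; the design names no such group, and no biological explanation was tested.

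Could the 1242 calls be an effect of dye and sequence at single features? If that were the whole cause, different features of a gene that share no sequence would be unrelated. They correlated at 0.242 (95% bootstrap interval 0.0726 to 0.396) over 132 genes, called or not. With row numbers as given the correlation was 0.1435 (permutation p = 0.1011). Whether features of a gene share sequence was not checked, and shared sequence would also give a positive correlation, so this cannot exclude that cause. Of 42 genes with a feature past the threshold, 29 had the same sign on both features (69.0%, exact interval 52.9% to 82.4%), and 4 had both features past it. If change of the whole transcript were the whole cause and both features responded to it alike, a correlation of 0.866 would follow. That value comes from the agreement of the same features between arrays and lies above the interval. Intensities were not available, so whether both features responded alike is unknown. A dye and sequence effect alone, or a mixture of it with change of the whole transcript, remains open. So do features that respond weakly or read different transcripts, and wrongly named features.

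Turning the sign of 1 array at a time gave at most 0 calls against 1242, but the 4 sign patterns are too few for a share under 0.05, and only the real pattern (1 of 4) reached the real count.

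The gathering of calls around HY5 was set against the rest of the genome. Of 6739 overlapping windows of 100 neighbouring named loci, 24 held 29 or more genes past the threshold, or 0.356%, and the highest held 31. Clustering at the usual level along the chromosomes was taken to need at least 5% of windows, a bound set before they were counted. The median window held 17 genes past the threshold. Without any clustering few windows would hold 29 or more, so a share below this bound was likely in advance and decides little. Overlapping windows share loci, so 0.356% is not a probability. Of the 24 windows, 12 did not overlap that around HY5, so gatherings of this size also occurred elsewhere. A stretch of linked sequence that differs between the mutant line and Ler may account for it, as may effects on neighbouring genes; neither was tested, and dye effects of single features apply here too.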
